A study of Mus musculus with 2 samples.

How the data were processed

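Gene and hashtag counts were deposited by the authors as filtered and unfiltered matrices of UMI counts per barcode, made with Cell Ranger 7.2.0 per the file headers. The submitters' processing notes name Cell Ranger 7.2 and the mouse build mm10. The gene annotation used for counting is not given in the sources used here. Per the labels' protocols, libraries were made with a high-throughput 3-prime droplet kit, after live GFP-negative cells had been sorted into mCherry-positive and mCherry-negative fractions that were tagged with 2 hashtag antibodies and recombined. The counts cover 32285 genes and 2 hashtags, and the vector, mCherry and GFP are not among the genes counted. Gene coordinates are from GENCODE M21 on GRCm38, where 32235 of the 32285 gene IDs were found.

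The filtered matrices are identical to the matching columns of the unfiltered ones and start at 500 gene UMIs per barcode. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were retained, which removed 441 and 594 barcodes on genes and 227 and 160 on mitochondrial UMIs in the Zbtb46-vector and empty-vector library. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 0 and 661 cells, so the cells with the highest scores were called instead, as many as an expected rate of 0.4% per 1000 barcodes gives (6.61% and 10.7%), and 1059 and 2844 otherwise retained cells were removed. A cell was assigned to a hashtag with at least 10 hashtag UMIs of which at least 80% were of 1 tag. This gave 5327 and 6443 mCherry-positive, 6689 and 14085 mCherry-negative cells, and 2779 and 2638 cells with both hashtags. Cells with both hashtags stayed in the main comparisons of the classes.

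Both libraries were clustered together without integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (python-igraph 0.11.9), which gave 27 clusters. Clusters were named from 28 fixed marker lists. A name needed at least 3 detected markers and no other class with more markers among the 10 leading genes by fold, clusters under 20 cells stayed unnamed, and clusters under 100 cells or of low depth also needed an own marker among these 10. A threshold set after seeing the data, at 25% of the monocyte/macrophage level of 7 myeloid genes, set aside the T cell-like cluster with myeloid transcripts for expression. The marker lists, gene lists, tests, the rule for named genes and most alternative settings were fixed before the data were examined.

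With 1 library per group no test between groups was possible. UMI counts were summed per library and class and divided by the class total (CPM). Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95%, and all cover counting error only. The 6 classes with at least 100 cells in each library and the most cells were compared. Gene lists (26 in all) were described by the median log2 ratio of members with at least 10 UMIs and its percentile among 10000 random lists of the same size matched on expression in 20 bins. This percentile describes these libraries and is not a test. For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. Free RNA was profiled from droplets under 100 UMIs, and its share was estimated from myeloid genes in T cells at 2.76% and 3.60% of UMIs.

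Named genes were, per class, the 8 highest and the 8 lowest by the interval bound nearest to 1, among genes at 50 CPM or more in either library with that bound beyond 1.5-fold. Mitochondrial, ribosomal protein, unnamed and variable-segment genes were left out, as were genes under 20% of their level in empty droplets. Zbtb46 was added in every class, and from each list up to 2 members at each end with at least 50 UMIs. Some genes that meet this rule are not reported here. For mCherry-positive against mCherry-negative cells 4 genes per direction were taken. Genes that answer a fixed question (Cd8a, Cd4, Foxp3, Pdcd1 and Mki67) were given as shares of cells.

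On simulated data the ratio intervals held the true ratio for 95.9% of 11017 genes, and for 98.5% of 200 genes changed 2-fold. The median log2 ratio was 1.00 for 100 raised and -0.97 for the lowered genes. Of 100 unchanged lists, 5 lay outside the central 95% of random lists. Counts were drawn independently for each gene with counting error only. The simulation thus checks the computation, not the spread of lists of genes regulated together or of pools of mice.

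Alternatives covered the cell filter, doublets, clustering, the naming of cells, the scaling of sums (TMM from edgeR 4.0.16, median of ratios from DESeq2 1.42.0, R 4.3.3), equal weight per cell, subtraction of free RNA, hashtag thresholds and thinning. Chosen after seeing the data were the settings that left out cells with both hashtags, took only cells with Y-linked UMIs and no Xist, added the unnamed clusters nearest to monocytes and macrophages, or changed which T cell-like cluster was used. Other tools were numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9.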

Results

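Single-cell RNA sequencing was carried out on 2 libraries of cells from mouse breast tumours of the PyMT-BO1 line, a GFP-labelled mammary carcinoma line. Tumours received lentiviral particles by intratumoral injection on days 9, 12 and 15 and were collected on day 16. The injected vector carried either Zbtb46, a zinc-finger transcription factor of conventional dendritic cells and endothelial cells, or no insert. Each library pooled 5 mice, and there was 1 library per group, so no difference below has a replicate check. Live cells without GFP were sorted into cells with and without the mCherry reporter of the vector. These sorted fractions were labelled with hashtag antibodies and combined. The question was what the delivery of Zbtb46 does to the stromal and immune cells of the tumour.

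The Zbtb46-vector library held 16533 cell barcodes with 149118493 gene UMIs, and the empty-vector library held 26771 barcodes with 202591663 gene UMIs. After filtering, 14806 and 23173 cells remained, at medians of 7419.5 and 5819 UMIs and 2644 and 2173 genes per cell. Ratios below are the Zbtb46-vector library over the empty-vector library unless stated, and fold values are followed by an exact 95% interval. All intervals cover counting error only.

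Zbtb46 itself (ENSMUSG00000027583, chromosome 2, 181387762 to 181459426, minus strand, GRCm38) was at 10.7 CPM (10.1 to 11.3) in the Zbtb46-vector library and 6.08 CPM (5.71 to 6.48) in the empty-vector library, a ratio of 1.76 (1.62 to 1.91) from 1388 and 973 UMIs. The level was highest in mature dendritic cell (DC)-like cells, at 441 against 283 CPM (1.56-fold, 1.34 to 1.82), and in conventional DC-like cells, at 104 against 73.9 CPM (1.41-fold, 1.24 to 1.62). Endothelial cell-like cells held 55.2 (39.1 to 75.8) and 42.7 CPM (24.9 to 68.4). NK cell-like cells had 10.1 against 1.62 CPM, a 6.24-fold difference (4.31 to 9.23). Of their 135 UMIs in the Zbtb46-vector library, 124 lay in mCherry-negative cells, and among mCherry-negative cells the ratio was 5.94 (4.07 to 8.86). Neutrophil-like cells had 4.23 CPM from 33 UMIs against 0.452 CPM from 5 UMIs (9.37-fold, 3.63 to 30.7), with 21 of the 33 UMIs in cells that carry both hashtags. In monocyte/macrophage-like cells, the largest class among mCherry-positive cells, it was 0.771 against 0.730 CPM, a ratio of 1.06 (0.693 to 1.59), so that no difference was detectable at this depth. Empty droplets held Zbtb46 at 6.51 and 7.77 CPM.

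Among mCherry-positive cells, Zbtb46 was at 6.63 against 1.39 CPM (4.77-fold, 3.66 to 6.28), and among mCherry-negative cells at 15.1 against 9.53 CPM (1.58-fold, 1.43 to 1.75). The mCherry-positive cells also differed in make-up. Fibroblast-like cells, at 12.2 CPM, were 20.03% of mCherry-positive cells in the Zbtb46-vector library and 0.838% in the empty-vector library. In the latter, 207 of 287 fibroblast-like cells carried both hashtags and are in neither tag. Mature DC-like cells with the reporter gave 70 and 22 UMIs. In mCherry-positive monocyte/macrophage-like cells 15 and 13 UMIs gave a ratio of 1.80 (0.799 to 4.11). Within each library, mCherry-positive cells held less Zbtb46 than mCherry-negative cells, with ratios of 0.440 (0.386 to 0.501) and 0.146 (0.112 to 0.187) over all classes, and conventional DC-like cells were 0.657% and 0.419% of mCherry-positive against 4.38% and 5.59% of mCherry-negative cells. Within classes of the Zbtb46-vector library the ratio was 1.55 (1.11 to 2.12) in conventional DC-like, 1.44 (1.09 to 1.87) in mature DC-like and 3.17 (1.12 to 7.33) in T cell-like cells. These values rest on only 35, 13 and 16 mCherry-positive cells, the last with 6 UMIs and from both T cell-like clusters. The ratio was 1.33 (0.583 to 3.12) in monocyte/macrophage-like, 1.06 (0.514 to 2.32) in endothelial cell-like, 0.843 (0.398 to 2.13) in fibroblast-like, 0.757 (0.273 to 1.70) in NK cell-like and 0.728 (0.0776 to 3.42) in neutrophil-like cells and 0.531 (0.181 to 1.89) in unnamed clusters, all with intervals that hold 1. In the empty-vector library it was 1.01 (0.594 to 1.62) in conventional DC-like, 0.852 (0.525 to 1.32) in mature DC-like and 0.486 (0.228 to 0.986) in monocyte/macrophage-like cells. A vector transcript that ends in viral sequence need not give 3-prime reads on the gene, so these values do not check delivery.

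**Figure D1:**
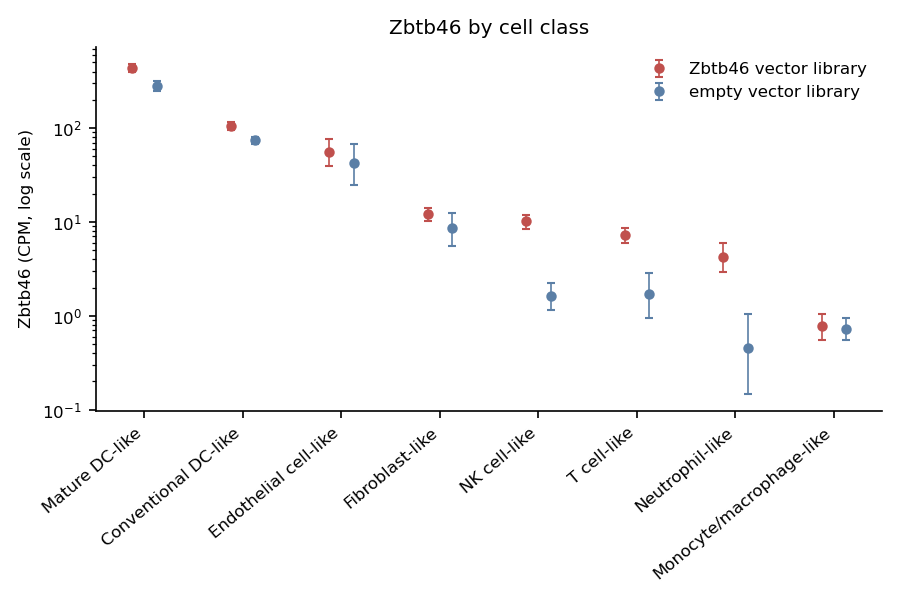
Zbtb46 level by cell class in CPM (log axis), 1 point per class and library, with exact Poisson 95% intervals that cover counting error only. Mature DC-like and conventional DC-like cells hold the most in both libraries, and monocyte/macrophage-like cells are at 0.771 and 0.730 CPM.

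After thinning each cell to 2000 UMIs, 53.4% (42.5 to 64.1) of mature DC-like cells in the Zbtb46-vector library and 40.5% (33.5 to 47.9) in the empty-vector library had a Zbtb46 UMI. In conventional DC-like cells the shares were 19.4% (15.4 to 23.9) and 15.5% (13.1 to 18.04), and in endothelial cell-like cells 4 of 54 and 3 of 50 cells had a UMI. Neutrophil-like cells gave 0.421% and 0.0892% at unthinned medians of 2661 and 1754.5 UMIs, and NK cell-like cells 2.38% and 0.233% at medians of 8891.5 and 6666 UMIs. Thinning left out 13 and 14 conventional DC-like cells and 2 and 10 mature DC-like cells. Without thinning, conventional DC-like cells gave 47.0% and 35.3%, at medians of 9713 and 6455 UMIs.

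The sorted GFP-negative cells of both groups were mainly myeloid. Monocyte/macrophage-like cells were 42.9% (42.1 to 43.7) against 48.9% (48.2 to 49.5) of kept cells in the Zbtb46-vector and the empty-vector library, and NK cell-like cells 9.00% (8.54 to 9.47) against 13.3% (12.9 to 13.7). Fibroblast-like cells were 6.38-fold more frequent (5.60 to 7.29) in the Zbtb46-vector library, at 7.90% (7.47 to 8.35) against 1.24% (1.10 to 1.39). T cell-like cells were 2.15-fold more frequent (1.99 to 2.32), at 10.9% (10.4 to 11.4) against 5.08% (4.80 to 5.37). Conventional DC-like cells were 2.49% (2.24 to 2.75) against 3.83% (3.58 to 4.08), and neutrophil-like cells 9.16% (8.70 to 9.63) against 10.7% (10.3 to 11.2).

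Rarer classes were mature DC-like cells at 0.608% and 0.863%, plasmacytoid DC-like cells at 0.432% and 0.613%, and mast cell or basophil-like cells at 0.783% and 1.77%. Endothelial cell-like cells were 0.378% (0.286 to 0.491) and 0.216% (0.160 to 0.284), and pericyte-like cells 6 and 17 cells. Unnamed clusters, most of them nearest to monocytes and macrophages, took 15.4% and 13.4%. With these added, monocyte/macrophage-like cells were 58.3% and 62.0%.

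The classes rest on different clusters in the 2 libraries. Monocyte/macrophage-like cells of the Zbtb46-vector library lay mostly in cluster 9 (3054 cells) and cluster 18 (1607), those of the empty-vector library in clusters 1 (3592), 13 (2189), 19 (2147) and 12 (1385). NK cell-like cells lay mostly in cluster 7 (1097 cells) and cluster 20 (2376), respectively. Among T cell-like cells, a cluster with few myeloid transcripts took 3.49% (3.20 to 3.80) against 2.96% (2.75 to 3.19) of kept cells, a ratio of 1.18 (1.05 to 1.32). A T cell-like cluster with myeloid transcripts took 7.42% (6.999 to 7.85) against 2.12% (1.94 to 2.32), and 76.8% and 36.2% of its cells carried both hashtags. Of the fibroblast-like cells of the empty-vector library, 72.1% carried both hashtags, and the fibroblast ratio was 23.4 without such cells.

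Several of these ratios moved or turned under other settings. Conventional DC-like cells were 2.37-fold more frequent in the Zbtb46-vector library when cells were classed by marker score and 4.25-fold when each library was clustered on its own. Neutrophil-like cells, at 0.852 in the main setting, gave 1.17 when at least 1000 genes per cell were required. The NK cell-like ratio of 0.677 was 0.389 at the higher clustering resolution, the monocyte/macrophage-like ratio of 0.877 was 0.528 by marker score, and the T cell-like ratio was 0.998 among cells with Y-linked UMIs and no Xist. The sort on GFP and the recombined mCherry fractions also act on each share.

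**Figure D2:**
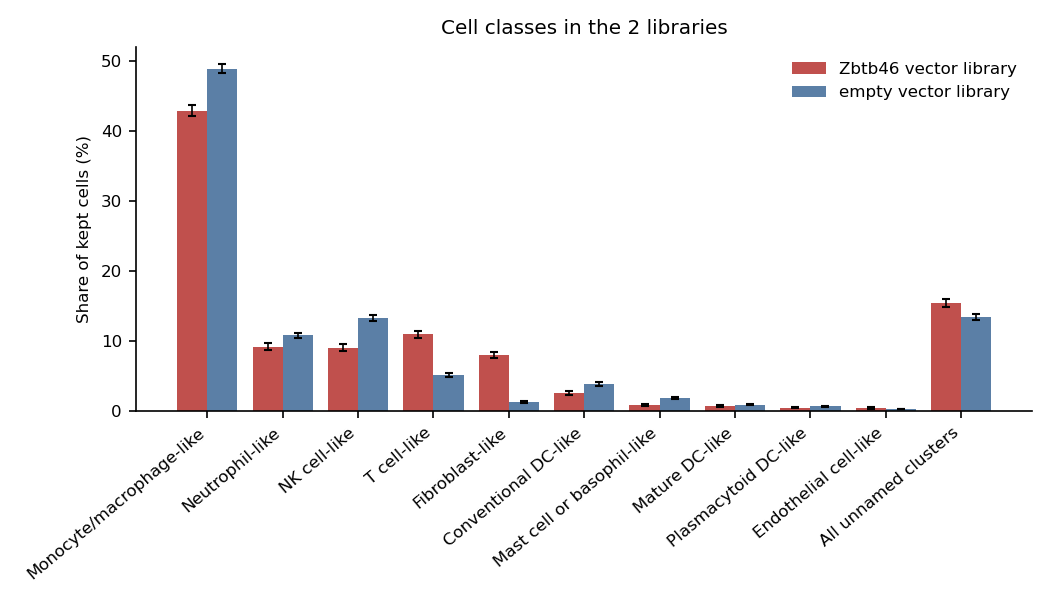
Share of kept cells in each class, in percent, for the Zbtb46-vector library (14806 cells) and the empty-vector library (23173 cells); bars are shares and error bars exact binomial 95% intervals for counting error only. Fibroblast-like cells are at 7.90% against 1.24% and T cell-like cells at 10.9% against 5.08%.

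Sex-linked transcripts separated the libraries. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), the RNA that silences an X chromosome in female cells, was at 564 against 14.7 CPM, and 4 Y-linked genes summed to 104 against 258 CPM. Cells with Xist and no Y-linked UMI were 59.4% and 1.67% of kept cells, and cells with Y-linked UMIs and no Xist 18.1% and 69.6%. Cells with both were 8.95% and 0.962%, where random pairs of cells of the Zbtb46-vector library would give 35.8%. The doublet step thus need not have removed every mixed droplet, and the share of mixed droplets among kept cells was not estimated. The sex of the mice is not given in the sources used here. Expression values below were therefore also computed among cells with Y-linked UMIs and no Xist.

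Over all kept cells, Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand), which encodes a secreted resistin-like protein of alternatively activated macrophages, was 69.8-fold (64.5 to 75.6) higher in the Zbtb46-vector library, at 277 against 3.97 CPM. It leads unnamed cluster 3, which held 1367 cells of that library and 107 of the other. The stromal chemokine Cxcl12 was 18.7-fold (17.2 to 20.4) higher, the collagen gene Col6a2 10.9-fold (10.2 to 11.6), the chemoattractant gene Rarres2 9.72-fold (9.30 to 10.2), the sphingomyelinase gene Smpd3 20.4-fold (18.6 to 22.3), Cpxm1 10.5-fold (9.77 to 11.3) and Tmeff2 10.4-fold (9.66 to 11.2). Lower were the immunoglobulin light-chain gene Igkc, 112-fold (98.1 to 128), with 90% of its UMIs in the empty-vector library held by 6 cells, the neutrophil gene Retnlg, 11.3-fold (10.7 to 12.0), Fcrls, 9.37-fold (8.69 to 10.1), Wfdc21, 6.83-fold (6.40 to 7.31), and Tmem37, 6.56-fold (6.16 to 6.99). The extracellular matrix list had a median log2 ratio of 2.05 over all cells, among which fibroblast-like cells were more frequent, and of -0.19 within fibroblast-like cells. The contractile list, at 1.59, the inflammatory fibroblast list, at 1.91, and the endothelial leukocyte adhesion list, at 1.56, lay with it above the central 95% of random lists, as did the interferon-gamma list at 1.61 and the type I interferon list at 0.58. The hypoxia and glycolysis list, at -0.31, and the proliferation list, at -0.64, lay below that range.

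The median gene had a log2 ratio of 0.23 over all cells, 0.25 in NK cell-like and 0.18 in T cell-like cells, and of at most 0.08 in the other classes. Scaling by TMM or median-of-ratios factors shifted log2 ratios by -0.26 and -0.23 over all cells, -0.26 and -0.25 in NK cell-like cells and -0.19 and -0.19 in T cell-like cells. List medians of these sets of cells should be read against those shifts.

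In monocyte/macrophage-like cells, interferon-gamma target genes were higher in the Zbtb46-vector library and cell-cycle genes lower. All 15 members of the interferon-gamma list were higher, with a median log2 ratio of 1.87 (percentile 100 of 10000 matched random lists). Ido1, a tryptophan-degrading enzyme, was 32.4-fold (17.2 to 68.5) higher, at 3.87 against 0.120 CPM, and the guanylate-binding protein Gbp4 (ENSMUSG00000079363, chromosome 5, 105115767 to 105139586, minus strand) 6.74-fold (6.48 to 7.01), at 241 against 35.8 CPM. The GTPase Tgtp1 was 7.43-fold (6.37 to 8.71) higher, the T cell chemoattractant Cxcl10 2.06-fold (2.03 to 2.08), at 1326 against 645 CPM, and Ciita, the transactivator of MHC class II genes, 1.80-fold (1.68 to 1.93). Of the proliferation list, 12 of 13 members were lower (median -0.94, percentile 0), with the mitotic kinase Cdk1 2.68-fold (2.51 to 2.86) and the cyclin Ccnb2 2.58-fold (2.37 to 2.82) lower.

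Proinflammatory genes were also higher in these cells, with a list median of 0.92 (percentile 100). Nos2, inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254, plus strand), was 5.67-fold (5.48 to 5.88) higher, at 278 against 48.9 CPM, and Ptgs2, cyclooxygenase 2, 3.90-fold (3.84 to 3.97), whereas the neutrophil chemokine Cxcl3 was 1.90-fold (1.82 to 1.99) lower. The costimulation list had a median of 0.63 (percentile 98.1), with Cd40 3.74-fold (3.57 to 3.92) higher and the ICOS ligand gene Icosl 2.16-fold (1.87 to 2.49) lower. Type I interferon genes had a median of 0.62 (percentile 98.7), with Ifit3 2.07-fold (2.005 to 2.13) lower. All 10 genes of the list on lentivirus sensing were higher (median 0.61), among them Samhd1, which limits reverse transcription, 3.34-fold (3.30 to 3.38), and the nucleic acid sensor Zbp1, 2.04-fold (1.998 to 2.09). The cytotoxic list had a median of 0.63, with the chemokine Ccl5 3.29-fold (3.22 to 3.35) higher.

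Macrophage genes of immunosuppression went both ways, with 8 of 14 members higher and a median of 0.09 (percentile 53.9). Cd274, which encodes PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095, plus strand), was 3.12-fold (3.07 to 3.17) higher, at 817 against 262 CPM, whereas the osteopontin gene Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) was 4.97-fold (4.89 to 5.05) lower, at 317 against 1577 CPM, and the folate receptor gene Folr2 4.98-fold (4.65 to 5.34) lower. The MHC class II list had a median of 0.10 (percentile 58.1), with H2-Ab1 at 1613 against 1156 CPM. The dendritic cell identity list had a median of 0.39 (percentile 96.2), with Xcr1 at 3.39 against 0.503 CPM and Flt3 at 1.49 against 1.57 CPM.

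Of the genes with the largest ratios in this class, Tmtc2 was 16.0-fold (14.4 to 17.7) higher, the actin-binding calponin gene Cnn3 13.8-fold (12.9 to 14.8), the neuregulin gene Nrg1 (ENSMUSG00000062991, chromosome 8, 31814551 to 32884029, minus strand) 10.6-fold (10.3 to 10.8), at 746 against 70.7 CPM, the activin subunit gene Inhba 10.1-fold (9.66 to 10.6), the itaconate-producing enzyme gene Acod1 6.66-fold (6.44 to 6.87) and Slc4a11 6.85-fold (6.32 to 7.44). Fcrls was 17.2-fold (15.2 to 19.6) lower, Syngr1 9.99-fold (8.87 to 11.3), Tmem37 9.75-fold (8.81 to 10.8), the TGF-beta pathway gene Pmepa1 9.07-fold (8.48 to 9.71), Ctla2b 6.57-fold (6.11 to 7.09) and the lipid carrier gene Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand) 5.70-fold (5.65 to 5.75), at 1003 against 5715 CPM. Nrg1 and Inhba are among the leading genes of cluster 9, and Fcrls, Apoe, Syngr1 and Tmem37 among those of cluster 1. Within clusters that held over 250 cells of each library the interferon-gamma list stayed higher, with medians of 1.34 in cluster 2, 1.92 in cluster 10, 0.79 in cluster 12 and 0.83 in cluster 13 of this class, and 1.23 in cluster 14, which is unnamed and outside the class. In the 4 clusters of the class the proinflammatory list had medians of -0.52, -0.09, 0.11 and -0.08. None of these lay above the central 95% of random lists, and that of cluster 2 lay below it. The proliferation list had medians of -0.04, -1.52, -0.45 and -0.57 in the 4 clusters, where cluster 2, at -0.04, is itself led by cell-cycle genes. Type I interferon medians there were 0.24, 0.89, 0.38 and 0.33, above the central 95% of random lists only in cluster 10. In cluster 14 the proinflammatory median was -0.20, the proliferation median 0.38 and the type I interferon median 0.38. Empty droplets had medians of 1.35 for the interferon-gamma and -0.67 for the proliferation list.

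The extracellular matrix and inflammatory fibroblast lists were also higher in monocyte/macrophage-like cells, at 1.39 and 1.37. Their medians in empty droplets were 1.501 and 1.78, and the inflammatory fibroblast median was -0.02 after subtraction of free RNA. The dissociation stress list was lower at -0.45 (percentile 0.46), with the chaperone gene Hspa1a 2.48-fold (2.32 to 2.66) lower. The lists that stayed within the central 95% of random lists in this class had medians of 0.43 (MHC class I), 0.04 (myeloid suppressor cell), 0.03 (lipid-associated macrophage), 0.38 (T cell exhaustion), 0.07 (naive and memory T cell), 0.24 (regulatory T cell), 0.21 (tip endothelial), 0.48 (leukocyte adhesion), 0.07 (endothelial junction), 0.27 (contractile), -0.14 (hypoxia and glycolysis) and -0.26 (mitochondrial genes). The hemoglobin list had 1 member above the UMI minimum and was not ranked.

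**Figure D3:**
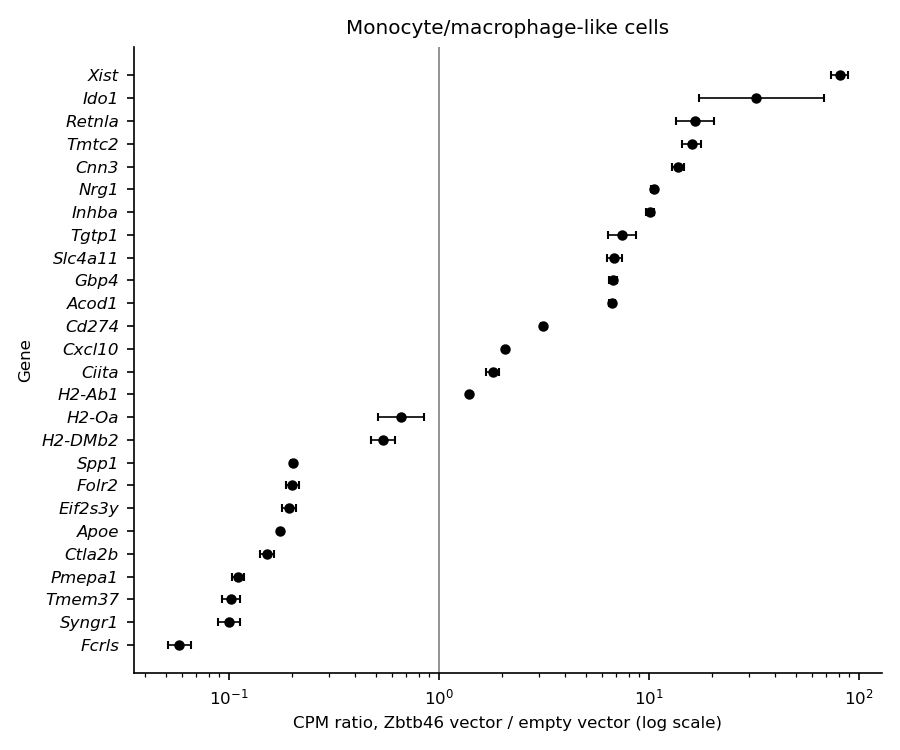
Ratio of CPM between the Zbtb46-vector and the empty-vector library in monocyte/macrophage-like cells (log axis) for the named genes with the largest ratios and for named members of the interferon-gamma, immunosuppressive macrophage and MHC class II lists, with 95% intervals for counting error only. Ido1 is at 32.4 and Fcrls at 0.0581.

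In NK cell-like cells, cell-cycle genes were lower in the Zbtb46-vector library and the exhaustion, naive and memory, and regulatory T cell lists higher. Cluster 21 of this class, led by Nusap1, Hist1h1b and Hist1h2ae, held 52 of 1332 and 356 of 3081 cells. Cluster 7 held 1097 and 349 cells and cluster 20 held 183 and 2376. A different mix of these clusters and a different level per cell were not separated for the values below. 12 of 13 proliferation genes were lower (median -1.02, percentile 0), with the survivin gene Birc5 3.31-fold (3.00 to 3.67), Ube2c 3.71-fold (3.31 to 4.16), Cdk1 3.21-fold (2.79 to 3.70), Cks1b 3.40-fold (3.09 to 3.75) and the histone gene Hist1h2ae 4.75-fold (4.12 to 5.51) lower. Higher were the triglyceride-synthesis gene Dgat1, 6.85-fold (6.27 to 7.48), the nuclear receptor gene Rora, 6.83-fold (6.07 to 7.70), the histone demethylase gene Kdm2b, 6.42-fold (6.01 to 6.85), and Cnnm2, 9.75-fold (8.22 to 11.6). The exhaustion list had a median of 0.75 (percentile 98.8), with the PD-1 gene Pdcd1 5.31-fold (4.48 to 6.31) higher, at 42.4 against 7.99 CPM. The naive and memory list, at 0.83, held the interleukin-7 receptor gene Il7r at 4.02-fold (3.31 to 4.89) and Bach2 at 3.49-fold (3.37 to 3.61), and the regulatory T cell list, at 1.002, held Ikzf2 at 3.62-fold (3.42 to 3.84).

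Interferon-gamma genes had a median of 0.90 in these cells (percentile 99.99), with Irf1 2.65-fold (2.43 to 2.90) and Gbp2 2.495-fold (2.19 to 2.85) higher and Socs1 1.44-fold (1.33 to 1.57) lower. The cytotoxic effector list, at 0.25, equalled the median gene. The dendritic cell identity list, at 0.93, held Zbtb46 itself and Dpp4 at 3.70-fold (2.37 to 5.91), and Id2 was 1.67-fold (1.62 to 1.71) lower. The leukocyte adhesion list was at 1.47, with Icam1 3.54-fold (3.14 to 3.999) higher, and the myeloid suppressor list at -0.56, with S100a8 at 5.18 against 22.4 CPM. The extracellular matrix list, at 1.60, and the inflammatory fibroblast list, at 1.19, ran with the empty droplets as above. Mki67 UMIs were found in 4.69% (3.61 to 5.98) and 8.41% (7.44 to 9.46) of cells thinned to 2000 UMIs, which left out 31 and 72 cells. Without thinning the shares were 11.3% and 17.4%.

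In neutrophil-like cells, interferon genes were higher and the neutrophil gene Retnlg lower in the Zbtb46-vector library. All 15 interferon-gamma genes were higher (median 1.64, percentile 100), with Gbp2 4.71-fold (4.53 to 4.90) and Gbp4 5.52-fold (4.87 to 6.27), and 13 of 14 type I interferon genes were higher (median 0.90), with Ifit1 2.67-fold (2.54 to 2.82). Retnlg (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496, plus strand), which encodes a resistin-like protein, was 10.9-fold (10.2 to 11.6) lower, at 130.0 against 1414 CPM, the chemokine-like gene Prok2 4.79-fold (3.90 to 5.92), Wfdc21 4.59-fold (4.21 to 5.00), and the protease inhibitor gene Csta2 4.78-fold (4.29 to 5.34). Nrg1 was 9.52-fold (8.77 to 10.3) higher, Cnn3 11.1-fold (9.06 to 13.8) and Tmtc2 14.4-fold (10.9 to 19.3), the same direction as in monocyte/macrophage-like cells, and Apoe 4.70-fold (4.57 to 4.83) lower. Apoe in empty droplets was at 1096 against 5164 CPM, a similar ratio.

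Proinflammatory genes had a median of 0.68, with Ptgs2 2.61-fold (2.55 to 2.68) higher and Cxcl3 2.35-fold (2.30 to 2.41) lower, and the lentivirus sensing list was at 0.78, with Samhd1 2.68-fold (2.60 to 2.76). The costimulation list was at 0.51, with Cd40 3.52-fold (3.01 to 4.13), but at 0.03 among mCherry-positive and 0.21 among mCherry-negative cells, within the random range in both. The mitochondrial genes were at -0.32 (percentile 3.1), and at -0.46 (percentile 1.4) among mCherry-negative cells. The hypoxia and glycolysis list was lower at -0.33, with the glucose transporter gene Slc2a1 1.80-fold (1.69 to 1.91), and the proliferation list at -0.56, although 0.92 among mCherry-positive cells. The regulatory T cell list, at -0.81, and the naive T cell list, at -0.54, rest on members at a few CPM, and the latter was 0.18 among members with at least 50 UMIs. The cytotoxic list, at 0.75, was -0.09 without cells that carry both hashtags. The extracellular matrix and inflammatory fibroblast lists were at 1.16 and 1.09, and the latter at -0.48 among cells with Y-linked UMIs and no Xist. Mki67 was found in 1.89% (1.13 to 2.97) and 2.94% (2.03 to 4.11) of the 951 and 1121 cells deep enough to thin.

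In fibroblast-like cells, adhesion, interferon and contractile genes were higher in the Zbtb46-vector library, and the extracellular matrix list, at -0.19 (percentile 20.9), was within the random range. The leukocyte adhesion list had all 5 members higher (median 0.86), with Icam1 3.67-fold (2.97 to 4.59) and Vcam1 1.83-fold (1.55 to 2.18). The interferon-gamma list was at 0.65 (percentile 99.97), with Gbp5 3.59-fold (2.09 to 6.68) higher and the chemokine Cxcl9 2.71-fold (2.37 to 3.09) lower, and the MHC class I list at 0.47, with B2m 1.80-fold (1.74 to 1.87). Type I interferon genes were at 0.55, with Rsad2 3.28-fold (2.35 to 4.72), and the contractile list at 0.72, with Myl9 3.24-fold (2.16 to 5.08) and Acta2 at 138 against 162 CPM. The lubricin gene Prg4 was 8.27-fold (7.86 to 8.71) lower, the connective tissue growth factor gene Ccn2 6.55-fold (5.87 to 7.31), Cilp 6.39-fold (5.71 to 7.15), the matrix Gla protein gene Mgp 6.20-fold (5.61 to 6.86) and Cthrc1 3.48-fold (3.33 to 3.63).

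The carbonic anhydrase gene Car4 was 32.7-fold (19.1 to 61.5) higher in these cells, Cadm2 29.1-fold (17.6 to 52.1), the collagen gene Col6a5 25.1-fold (16.2 to 41.2) and the leukotriene C4 synthase gene Ltc4s 10.1-fold (6.74 to 15.8). The stress list was at 0.55, with Egr1 2.06-fold (1.99 to 2.13), and the tip endothelial list at 0.50, with Flt1 8.11-fold (3.88 to 20.4). The proliferation list was lower at -0.52, with Tyms 2.69-fold (1.93 to 3.73), and Mki67 was found in 2.13% (1.35 to 3.17) and 1.83% (0.597 to 4.22) of thinned cells. The direction for Mki67 turned to 4.96% and 7.32% without thinning, and to 1.39% and 1.77% at 1000 UMIs. Lower lists of immune genes were myeloid suppressor genes, at -0.47 but 0.20 after subtraction of free RNA, and cytotoxic genes, at -0.52, with S100a8 at 24.3 against 59.8 CPM and Gzma at 5.66 against 19.7 CPM. Only 287 fibroblast-like cells came from the empty-vector library, 207 of them with both hashtags. Without such cells, Thbs4, otherwise 5.25-fold (4.35 to 6.33) lower, had a log2 ratio of 1.17, the exhaustion list turned from 0.9997 to -0.82, and 3 lists lay above the central 95% of random lists in place of 9. The contractile list was -0.28 among cells with Y-linked UMIs and no Xist, and the naive T cell list, at 0.80, was -0.07 with doublets kept.

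Conventional DC-like cells of the Zbtb46-vector library had higher maturation and interferon-gamma genes and lower cell-cycle genes. The costimulation list had 8 of 9 members higher (median 1.09, percentile 100), with the OX40 ligand gene Tnfsf4 4.76-fold (2.52 to 9.51) and Ccr7, the lymph node homing receptor, 4.17-fold (3.75 to 4.64), at 302.5 against 72.5 CPM. The interferon-gamma list was at 1.48 (percentile 100), with Gbp2 5.55-fold (5.13 to 6.01). The proliferation list was at -1.32 (percentile 0), with Cdk1 4.41-fold (3.19 to 6.24) lower. Xcr1, the chemokine receptor of cDC1 cells (ENSMUSG00000060509, chromosome 9, 123852315 to 123862029, minus strand), was 4.62-fold (3.74 to 5.77) lower, at 25.1 against 116 CPM, and Cd209a, a lectin gene of cDC2 and monocyte-derived cells, 4.37-fold (3.88 to 4.93) higher, at 248 against 56.9 CPM.

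The dendritic cell identity list thus had a median of -0.14 (percentile 3.5), and Id2 was 2.39-fold (2.27 to 2.52) lower. MHC class II genes were at -0.14, with 8 of 9 members lower and Cd74 the 1 higher, at 9835 against 9121 CPM. Cd274 was 3.14-fold (2.96 to 3.34) higher and Trem2 5.02-fold (3.63 to 7.12) lower. The type I interferon list was at 0.69, with Zbp1 2.25-fold (2.05 to 2.47), the lentivirus sensing list at 0.55, and the naive and memory list at 0.80. Tmtc2 was 10.6-fold (9.59 to 11.8) higher, the oxysterol hydroxylase gene Cyp7b1 7.78-fold (6.48 to 9.38) and Abtb2 6.30-fold (5.64 to 7.06), and Apoe was 7.93-fold (7.28 to 8.66) lower. The class came from 1 cluster with cDC1 and cDC2 genes and 368 and 887 cells, so that a different mix of both kinds and a different level per cell cannot be separated here. The extracellular matrix list was at 1.40, and the inflammatory fibroblast list, at 1.39, was -0.88 among members with at least 50 UMIs. Mki67 was found in 2.82% (1.36 to 5.12) and 5.50% (4.08 to 7.22) of thinned cells.

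Expression in T cells was compared in the cluster with few myeloid transcripts, 517 and 686 cells. Xcl1, the ligand of Xcr1 (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527, minus strand), was 14.6-fold (12.2 to 17.5) lower in the Zbtb46-vector library, at 39.1 against 569 CPM, the Ly49 receptor genes Klra7 14.2-fold (10.7 to 19.4) and Klra1 13.7-fold (9.28 to 20.9), the NK1.1 gene Klrb1c 7.73-fold (5.61 to 10.9), the chemokine Ccl1 12.4-fold (9.35 to 16.8) and Cd7 6.41-fold (4.55 to 9.22). Xcl1 and Klra7 are also among the leading genes of NK cell-like cluster 20, which held 183 cells of the Zbtb46-vector and 2376 of the empty-vector library. Whether NK cells within the T cell-like cluster contribute to these ratios was not tested. Higher in the Zbtb46-vector library were the phospholipase-like gene Plcl1, 7.63-fold (5.74 to 10.3), Dgat1, 6.69-fold (5.40 to 8.37), the serpin gene Serpine2, 6.83-fold (4.93 to 9.69), the stress-response gene Gadd45b, 5.08-fold (3.80 to 6.90), and the elongation factor gene Ell2, 4.48-fold (3.60 to 5.62). The interferon-gamma list was at 0.80 (percentile 99.86), with Irf1 2.69-fold (2.24 to 3.23) and Gbp2 2.47-fold (1.93 to 3.20) higher.

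The exhaustion list was at -0.07, the cytotoxic list, with 9 of 11 members higher, at 0.53 and the proliferation list at -0.07, all within the central 95% of random lists. Type I interferon genes were at -0.24, with Ifit3 2.004-fold (1.62 to 2.49) lower, and MHC class II genes at -0.52, with H2-Eb1 1.59-fold (1.20 to 2.11) lower. The myeloid gene Lyz2 was also lower in these cells, at 47.3 against 146 CPM. The type I interferon and MHC class II lists both turned with the cluster with myeloid transcripts added, to 0.05 and 0.15. The junction list, at -1.05, had 4 members, among them the quiescence factor gene Klf2, 3.78-fold (3.00 to 4.80) lower, and was 0.52 among cells with Y-linked UMIs and no Xist. The extracellular matrix list was at 1.10.

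Most cells of this cluster were of the CD8 kind. After thinning to 2000 UMIs, Cd8a was found in 59.2% (54.7 to 63.6) of 488 cells and 50.2% (46.3 to 54.2) of 647, Cd4 in 3.69% (2.20 to 5.77) and 0.309% (0.0375 to 1.11), and Pdcd1 in 43.2% (38.8 to 47.8) and 41.6% (37.7 to 45.5). Foxp3 UMIs were found in 2 cells and in none, with an upper bound of 0.569% for cells with a UMI at this depth in the empty-vector library; cells that express the gene below this depth are not counted. Neutrophil-like cells gave 0% and 0.178% for Cd8a, 0.105% and 0.178% for Cd4, 0.421% and 0.178% for Pdcd1 and 0.105% and 0% for Foxp3, at medians of 2661 and 1754.5 UMIs against 6112 and 3609.5 in the T cell-like cells. Thinning left out 29 and 39 cells. Without it, Cd8a was found in 80.7% and 66.9%, Cd4 in 6.19% and 1.17%, Foxp3 in 0.774% and 0.146%, and Pdcd1 in 74.5% and 55.2%. Mki67 was found in 4.51% (2.85 to 6.75) and 1.85% (0.962 to 3.22) of T cell-like cells thinned to 2000 UMIs, in 1.17% (0.431 to 2.53) and 0.732% (0.238 to 1.70) of those thinned to 1000 UMIs, and in 2.98% (2.56 to 3.44) and 5.66% (5.24 to 6.11) of thinned monocyte/macrophage-like cells.

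**Figure D4:**
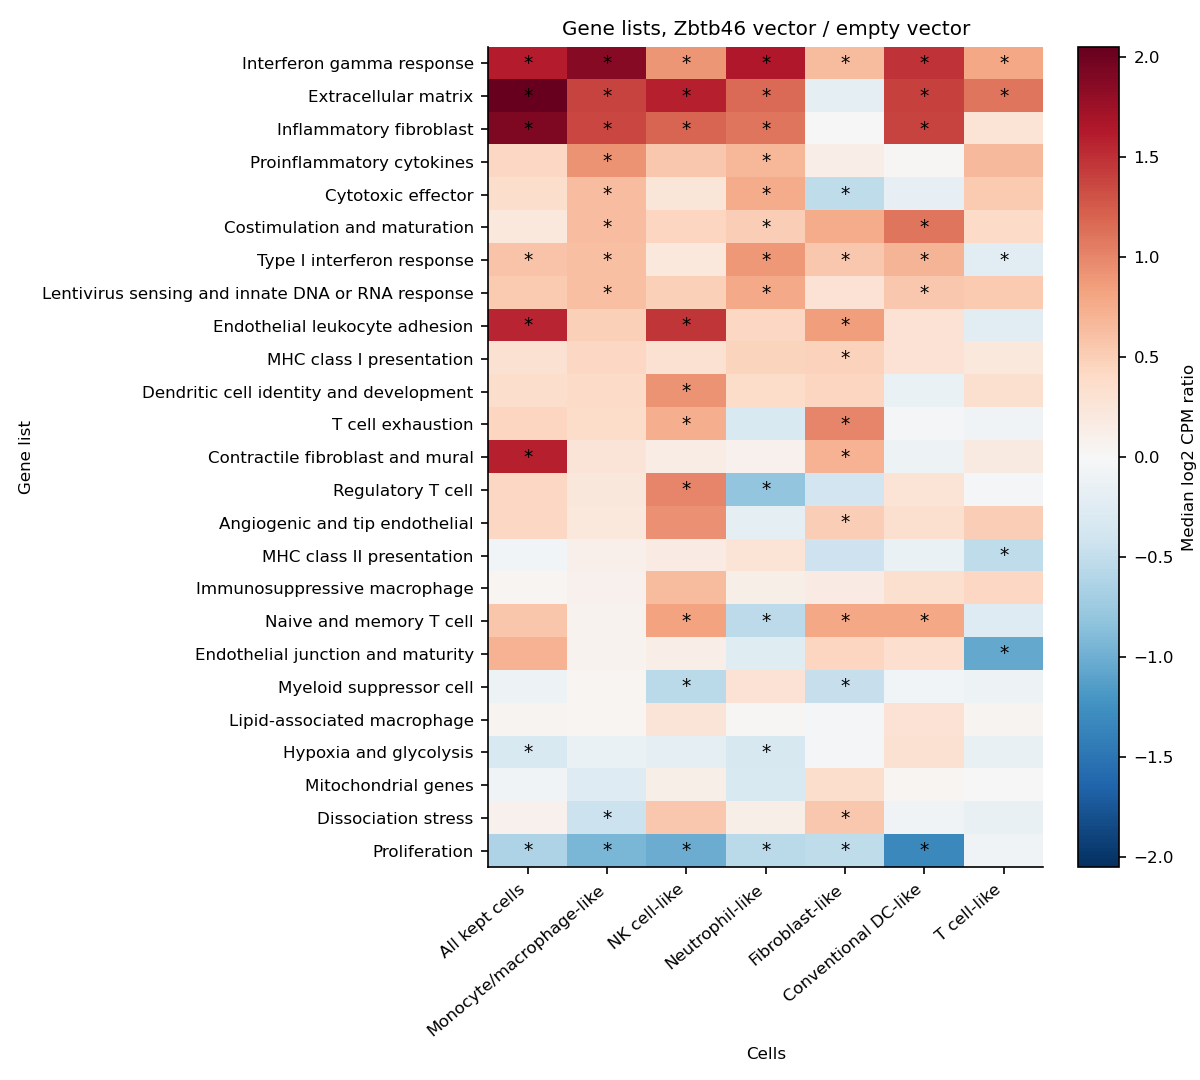
Median log2 CPM ratio of each gene list (vertical axis) in each set of cells (horizontal axis), Zbtb46-vector over empty-vector library; an asterisk marks a median outside the central 95% of matched random lists. The interferon-gamma list lies above that range in every column, from 0.65 in fibroblast-like to 1.87 in monocyte/macrophage-like cells.

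Monocyte/macrophage-like cells were the largest class among cells that carried the vector reporter, and few of these cells were lymphocytes. Monocyte/macrophage-like cells were 46.2% (44.8 to 47.5) of mCherry-positive cells in the Zbtb46-vector library and 64.7% (63.5 to 65.8) in the empty-vector library, against 48.3% and 42.2% of mCherry-negative cells. NK cell-like cells were 0.601% and 1.51% of mCherry-positive cells against 18.8% and 20.9% of mCherry-negative cells, and T cell-like cells 0.300% and 0.124% against 10.99% and 6.99%. Fibroblast-like cells were 20.03% and 0.838% of mCherry-positive cells against 0.389% and 0.185% of mCherry-negative cells. Of all fibroblast-like cells, 6.41% in the Zbtb46-vector and 72.1% in the empty-vector library carried both hashtags and are in neither tag. The 0.838% rests on 54 cells after this unequal exclusion. Unnamed clusters took 25.7% and 21.9% of mCherry-positive cells. The sort set how many cells carry each tag, so only the make-up within a tag is compared.

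Monocyte/macrophage-like cells with and without the reporter lay in different clusters. In the Zbtb46-vector library cluster 18 took 23.1% of mCherry-positive and 3.14% of mCherry-negative cells and cluster 9 8.92% and 34.3%, and in the empty-vector library cluster 1 took 40.9% and 4.04%. Summed over the class, cell-cycle and lipid-associated genes were higher in mCherry-positive than in mCherry-negative cells of both libraries. The proliferation list had medians of 2.5001 in the Zbtb46-vector and 1.76 in the empty-vector library, and the lipid-associated macrophage list 1.90 and 1.45. In the Zbtb46-vector library the chemokine Pf4 was 18.6-fold (17.4 to 19.9) higher, the replication gene Pclaf 13.7-fold (11.9 to 15.8), the topoisomerase gene Top2a 12.9-fold (11.3 to 14.9) and Birc5 13.3-fold (11.1 to 16.1). In the empty-vector library the resident-macrophage genes Ccl8 and Folr2 were 19.0-fold (17.8 to 20.4) and 17.3-fold (15.4 to 19.5) higher, Cbr2 19.4-fold (16.1 to 23.4) and Vcam1 11.2-fold (10.3 to 12.1). Lower in mCherry-positive cells were the haptoglobin gene Hp, 13.3-fold (11.6 to 15.3) in the Zbtb46-vector and 18.7-fold (16.6 to 21.3) in the empty-vector library, Ifitm6 11.7-fold (10.7 to 12.8), Dmkn 12.1-fold (10.4 to 14.04) and the coagulation factor gene F5 16.4-fold (13.4 to 20.2) in the Zbtb46-vector library, and Plac8 16.1-fold (15.8 to 16.5), Chil3 15.9-fold (15.2 to 16.7) and Wfdc21 16.6-fold (14.1 to 19.7) in the empty-vector library.

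The interferon-gamma list was lower in mCherry-positive than in mCherry-negative monocyte/macrophage-like cells of both libraries, at -0.80 and -0.69, and the immunosuppressive macrophage list higher, at 0.78 and 0.99. MHC class II genes were at -0.09 in the Zbtb46-vector library and -1.16 in the empty-vector library. Between the libraries, the interferon-gamma list was higher in the Zbtb46-vector library among mCherry-positive monocyte/macrophage-like cells, at 1.68, and among mCherry-negative ones, at 1.98. The dendritic cell identity list was at 0.71 (percentile 99.4) among these mCherry-positive and 0.31 (percentile 91.7) among these mCherry-negative cells. In the same order, the MHC class I list was at 0.75 (percentile 99.7) and 0.32 (percentile 68.9). The MHC class II list was at 0.65 (percentile 98.5) and -0.23 (percentile 21.3). Cells with both hashtags, 18.8% and 11.4% of kept cells, were in neither set.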

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

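Chosen only after the results were seen were the tests of the matrix genes against the free-RNA level, all 3 tests of the T cell-like share, and the settings that left out cells with both hashtags or took only cells with Y-linked UMIs and no Xist.

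The interferon-gamma list was higher in monocyte/macrophage-like cells of the Zbtb46-vector library, at a median log2 ratio of 1.87. The sex of the mice as its cause is argued against by the 2.02 found among cells with Y-linked UMIs and no Xist, and free RNA by the 1.87 left after subtraction, although empty droplets themselves had a median of 1.35. The lower medians of 0.90 in NK cell-like and 0.80 in T cell-like cells were 0.90 and 0.87 after subtraction. A difference between the 2 library preparations or pools of mice cannot be told apart from the vector, since there was 1 library per group. An effect of Zbtb46 delivery therefore stays among the open explanations, untested.

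Extracellular matrix genes were higher in 5 classes other than fibroblast-like cells, with a median of the class medians of 1.39. Free RNA from the more numerous fibroblasts is a candidate explanation. Of 60 gene and class pairs of the Zbtb46-vector library, 15% (9 pairs) held more UMIs than free RNA would give. Fn1 in monocyte/macrophage-like cells was among them, at 13258 UMIs against 1151. In the T cell-like cells that set the free-RNA share, only Col6a1 held more, at 10 UMIs against 8.11, and Col1a1 held 35 against 60.3. A share set too high lowers this count, so the count alone cannot decide. The value chosen at the start for this test, the list median after subtraction, could not be computed with so few members left, so this count took its place. Droplets mixed with a fibroblast of the other sorted fraction are argued against, since the median was 1.24 without cells that carry both hashtags. Fibroblast-like cells of the Zbtb46-vector library were 91.2% mCherry-positive, so their pairs with other mCherry-positive cells would carry a single hashtag and stay in. For monocyte/macrophage-like cells, of which 2460 of 6349 were mCherry-positive there, this setting cannot decide. No biological explanation was tested.

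The T cell-like share was 2.15-fold higher in the Zbtb46-vector library. Droplets that hold a T cell and a myeloid cell may account for it: in the T cell-like cluster with myeloid transcripts 32.4% (29.7 to 35.3) of its cells had both Xist and Y-linked UMIs, against 35.8% given by random pairs of cells and 1.93% in the other cluster. Free RNA is argued against by Lyz2 at 1250.5 CPM there, where it would give 55.2 CPM. A higher number of single T cells as the whole cause is argued against by the ratio of 1.18 (1.05 to 1.32) in the cluster with few myeloid transcripts. A pair of cells that adhered in the tumour would come from the same mouse and the same sorted fraction, with a single sex and a single hashtag. The cells with both Xist and Y-linked UMIs argue against such pairs for those cells. Of this cluster, 76.8% of cells in the Zbtb46-vector and 36.2% in the empty-vector library carried both hashtags. These would argue against such pairs only where a second hashtag marks a second cell, which cannot be taken as given. Kept cells with both hashtags had a median of 6776 UMIs in the Zbtb46-vector library, against 7880 in mCherry-positive and 7303 in mCherry-negative cells. In the empty-vector library these medians were 10566, 7109 and 4977. For the remaining cells of the cluster the origin of the pairs was not told apart.

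Some list medians went opposite ways in mCherry-positive and mCherry-negative cells, and the difference between these was not tested. In monocyte/macrophage-like cells the MHC class II list was at 0.65 in mCherry-positive and -0.23 in mCherry-negative cells. In neutrophil-like cells the proliferation list was at 0.92 and -1.16, the cytotoxic list at 0.56 and -0.27, and the contractile list at 0.43 and -0.23.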

How the results depend on the processing

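Settings chosen after seeing the data were those without cells that carry both hashtags, with Y-linked UMIs and no Xist, with unnamed clusters added and on T cell-like clusters. No paired analysis was possible because each group has 1 library. Of 66 share ratios under other settings 37 stayed, 25 moved and 4 turned. With unnamed clusters added only the monocyte/macrophage-like share differed, and with the T cell-like cluster alone only the T cell-like share. Ratios of the other classes there, such as 0.677 for NK cell-like cells, equal the main setting by construction. They are counted among the 37 and do not show stability. Of 1469 list medians 929 stayed, 520 moved and 20 turned. Ratios and medians that stayed lay within the 95% counting interval of the main value. Those that turned lay on the other side of no difference. For list medians a turn was counted only where the main median lay outside the central 95% of random lists and was at least 0.2 in size. Sign changes of other lists are among those that stayed or moved, so the 20 are not every change of direction. Of 915 gene ratios 600 stayed, 314 moved and 1 turned. The interferon-gamma medians turned under no setting. The cause of the values below was not tested; lists above and below are those outside the central 95% of random lists.

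Leiden resolution 0.5 gave share ratios of 0.919 (monocyte/macrophage-like), 0.926 (neutrophil-like) and 0.552 (conventional DC-like), and resolution 2 gave 0.797 (monocyte/macrophage-like), 0.389 (NK cell-like) and 0.944 (neutrophil-like). Each library clustered on its own gave 0.809, 0.982 (neutrophil-like) and 4.25 (conventional DC-like). Marker scores gave 0.528 (monocyte/macrophage-like), 5.26 (fibroblast-like), 2.37 (conventional DC-like) and 1.55 (T cell-like). Neutrophil-like cells gave 0.769 under the looser and 1.17 under the stricter cell filter and 0.785 with doublets kept, which also gave 1.82 for T cell-like cells. Unnamed clusters added gave 0.940 for monocyte/macrophage-like cells, and the T cell-like cluster with few myeloid transcripts alone gave 1.18. Every barcode with at least 200 genes gave a median of 6152 UMIs in the empty-vector library.

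Without cells that carry both hashtags, share ratios were 0.961 (monocyte/macrophage-like), 0.723 (NK cell-like), 23.4 (fibroblast-like) and 1.29 (T cell-like). Lists below were 2 in neutrophil-like, 6 in fibroblast-like and 2 in conventional DC-like cells, lists above 3 in fibroblast-like cells; the cytotoxic median was -0.092 in neutrophil-like cells, the exhaustion median -0.82 in fibroblast-like cells and the Thbs4 log2 ratio 1.17. With doublets kept, the cytotoxic median was -0.94 in neutrophil-like cells, the exhaustion and naive T cell medians -0.30 and -0.069 in fibroblast-like cells, with 3 lists above there and 2 below in conventional DC-like cells.

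Among cells with Y-linked UMIs and no Xist, share ratios were 0.971 (monocyte/macrophage-like), 0.876 (NK cell-like), 0.948 (neutrophil-like), 7.30 (fibroblast-like), 0.808 (conventional DC-like) and 0.998 (T cell-like). Lists below were 4 over all cells, 5 in monocyte/macrophage-like, 4 in NK cell-like, 2 in neutrophil-like, 5 in fibroblast-like and 2 in conventional DC-like cells, and lists above 5 in fibroblast-like and 1 in T cell-like cells. Medians that turned were 0.13 (naive T cell) and -0.48 (inflammatory fibroblast) in neutrophil-like cells, -0.23 (exhaustion) and -0.28 (contractile) in fibroblast-like cells and 0.52 (junction) in T cell-like cells. Both T cell-like clusters together gave 10 lists above, with 0.049 for type I interferon and 0.15 for MHC class II.

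Free RNA subtracted gave -0.023 for the inflammatory fibroblast list in monocyte/macrophage-like cells, 0.20 for the myeloid suppressor list in fibroblast-like cells and 1 list below in NK cell-like cells. Members with at least 50 UMIs gave 0.18 (naive T cell, neutrophil-like) and -0.88 (inflammatory fibroblast, conventional DC-like), 5 lists below in fibroblast-like and 2 in conventional DC-like cells, and 1 above in T cell-like cells. Within mCherry-negative cells the cytotoxic median was -0.27 in neutrophil-like cells, with 2 lists below there and 4 in conventional DC-like cells; within mCherry-positive neutrophil-like cells medians were 0.068 (naive T cell), 0.024 (regulatory T cell) and 0.92 (proliferation), with 1 list below.

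With 1 hashtag at 95% or more, the mCherry-positive over mCherry-negative Zbtb46 ratio was 0.316 in the Zbtb46-vector and 0.101 in the empty-vector library, and monocyte/macrophage-like cells were 52.5% and 68.2% of mCherry-positive cells. Without thinning, differences in percent of cells with a UMI were 19.2 (Pdcd1, T cell-like), 11.7 (Zbtb46, conventional DC-like), 18.9 (Zbtb46, endothelial cell-like), and for Mki67 -5.63 (monocyte/macrophage-like), -6.14 (NK cell-like), -2.36 (fibroblast-like), -6.41 (conventional DC-like) and 7.09 (T cell-like). At 1000 UMIs they were 1.66 (Cd4, T cell-like), and for Mki67 -1.78, -1.88 (NK cell-like) and 0.440 (T cell-like).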

Other observations

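The genes and clusters below were singled out after their values were seen, and no explanation was tested. Igkc, an immunoglobulin light-chain gene made in bulk by plasma cells, had 30452 UMIs in the empty-vector library and 221 in the Zbtb46-vector library, and 6 cells of the former held 90% of them. Within the plasmacytoid DC-like cluster it was at 45722 CPM in the empty-vector and 161 CPM in the Zbtb46-vector library, and no cluster was named for plasma cells or B cells. Cluster 3, led by Retnla, Cd163, Ccl24 and Ccl8, genes of alternatively activated tissue macrophages, held 9.23% of cells in the Zbtb46-vector and 0.462% in the empty-vector library. Of its 1367 cells in the Zbtb46-vector library, 45.8% carried both hashtags. Cluster 16, led by Hspa1a, Spp1, Mmp12, Gpnmb and Arg1, held 0.426% and 8.77%. With 1 library per group, a cluster found mostly in 1 library may be that library and not a cell type.

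Cells with Xist were rare in the empty-vector library, at 1.67% of kept cells, and not spread evenly. They were 17.8% of its 107 cells in cluster 3, 16.5% of 109 in cluster 9, 17.2% of 116 in cluster 18 and 15.0% of its fibroblast-like cells, counting cells with Xist and no Y-linked UMI. Cluster 26, with 46 cells of the empty-vector library led by Hmga2, Crabp1 and Ereg, had Xist alone in 69.6%.

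Gm42418, an unnamed gene that overlaps ribosomal RNA sequence, was at 12709 CPM in the Zbtb46-vector and 4871 CPM in the empty-vector library, and at 20189 and 7376 CPM in empty droplets. Tmsb4x, the thymosin beta 4 gene, was at 15615 and 24965 CPM.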
